A study of Vitis vinifera with 60 samples.

How the data were processed

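RNA was measured in berry pericarp, which the labels describe as entire berries without their seeds, of 5 white-skinned grapevine cultivars (Vitis vinifera): Garganega, Glera, Moscato bianco, Passerina and Vermentino. The vines grew in the same experimental vineyard in the 2011 season, and berries were taken at 4 growth stages. Per the labels' protocols, about 400 mg of tissue went into each extraction, and non-directional TruSeq libraries were sequenced on a HiSeq 1000. The labels list 60 libraries, 3 for each of the 20 combinations of cultivar and stage.

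The values used here are FPKM (fragments scaled by transcript length and by the number of mapped fragments) that the authors deposited as 1 table with 20 columns. Per the name and header of the deposited table, each column holds the authors' mean for 1 cultivar at 1 stage. Per the submitters' processing notes, TopHat2 2.0.6 and Cufflinks 2.0.2 were used. The role of each tool, the genome build, the annotation and the order of averaging and normalization are not given in the sources used here. All 20 columns were matched to their group by name, and 0 columns were left over. Values of single libraries were not analysed here. The spread between the 3 libraries of a group is therefore unknown.

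The table has 29287 rows with identifiers that begin with VIT. Each row is called a gene below, although 608 rows join several identifiers. The libraries do not mark strand, so fragments of overlapping genes and of antisense partners cannot be told apart, and near-identical copies can share fragments. Sequencing depth is unknown. FPKM were fractional, and 2099 of the 463232 values above 0 lay under 0.001, so whole reads could not be recovered and no counting interval is given. Values of exactly 0 also occur in genes with very high values in other columns. A 0 is therefore given as listed at 0, and no fold is given against a group listed at 0 throughout.

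The files do not pair the identifiers with gene names. A table of 29591 annotated genes of the assembly ASM3070453v1 was searched for them, and 0 identifiers matched. Gene names, functions and positions are left out for that reason. The 34 gene lists fixed before the data were examined, and their set tests, were not run, because they depended on names. The rule fixed for naming genes took, for each transition, called genes with the same direction in all 5 cultivars and a mean of at least 10 FPKM at the higher stage, in order of their change. It also asked for an informative name, a condition that was dropped here, and without names at most 2 identifiers that rose and 2 that fell are printed for each transition. For cultivars, the 2 genes with the widest margin above and the 2 with the widest margin below the others are given. Of the most abundant genes, which the rule also listed, 2 are named.

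Genes with at least 1 FPKM in at least 1 column were kept, which left 20833. Values were taken as log2(FPKM + 1), so a change understates the fold of genes with low FPKM. Adjacent stages were compared with limma 3.58.1 (moderated statistics with a trend) in R 4.3.3. All 20 columns entered 1 model with stage and cultivar as terms, which left 12 residual degrees of freedom. The cultivar served as the replicate (n = 5 cultivars at each stage). The cultivar term removes differences between cultivars that hold at all stages, while the SD over cultivars printed below include them. The p-values thus set a stage change against how unevenly the cultivars changed, pooled over all stages. They do not use the spread between libraries. A value out of line at a stage outside a transition can therefore raise the p of that transition. A gene was called when the Benjamini-Hochberg adjusted p was under 0.05 and the change was at least 2-fold on that scale. An interaction of cultivar and stage could not be tested with 1 value per combination. Differences between cultivars are described by fixed sizes without a test. The position of a column along ripening was its projection on the line from the mean Pea profile to the mean Harv profile of the other 4 cultivars, with 0% at Pea and 100% at Harv.

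The procedure was tested on simulated data for the comparison of Touch with Soft over 20833 genes, with the real means and spread. Of 100 genes changed 2-fold, 82% passed the adjusted p and 49% were called. A true change of exactly 2-fold lies at the fold limit of a call, so that limit largely set the 49%. Of 100 genes changed 4-fold, 93% were called. The changed genes were drawn only from those with a mean of at least 10 FPKM over the columns. These shares therefore do not cover genes with lower FPKM. Far fewer genes were changed than the 12507 that passed the adjusted p from Touch to Soft in the data. The adjustment thus differed, and the shares do not carry over directly. Among 20633 unchanged genes 0 were called and 7 passed the adjusted p. All 30 genes planted with a margin between cultivars were recovered. This was fixed in advance, since they were set above all values of the other cultivars by more than the rule asks.

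Alternatives fixed before the data were examined were other pseudocounts (0.1 and 5), no filter or a filter of 5 FPKM, columns scaled to equal medians, quantile normalization, no cultivar term, moderation without a trend, a test against a 2-fold change (limma's treat), the 2 stages alone, other fold sizes, and leaving out each cultivar or stage in turn. Added after seeing the data was a scaling by the sum over all but the 100 most abundant genes, a fixed set with the highest mean over the columns. A run without abundant genes that have a value of 0 was also added. So were the counts of changes shared by cultivars with each cultivar left out.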

Results

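The study followed messenger RNA in the pericarp of 5 white Italian grapevine cultivars from small green berries to harvest. The stages were pea-sized berries (Pea), berries beginning to touch in the bunch (Touch), soft berries (Soft) and berries ripe for harvest (Harv). Each of the 20 combinations of cultivar and stage had 3 libraries, of which the table holds the authors' mean FPKM. Means ± SD below run over the 5 cultivars at a stage, and no error between libraries can be given. Of 29287 genes, 3002 were listed at 0 in all columns and 20833 reached 1 FPKM in at least 1 column.

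Fewer genes reached 1 FPKM in riper berries. At Pea, 17914 ± 252 genes reached 1 FPKM (SD, n = 5 cultivars), and at Touch 17297 ± 337 did. At Soft the number was 16071 ± 45.5 and at Harv 15800 ± 154. The lowest cultivar at Touch, with 16938 genes, stood above the highest at Soft, with 16133. The most abundant genes held a larger share at Soft and Harv than at Pea. The 100 most abundant genes, chosen anew in each column, held 19.1% ± 0.65 of the summed FPKM at Pea and 25.5% ± 4.1 at Touch. They held 40.4% ± 5.6 at Soft and 43.3% ± 3.9 at Harv. The lowest shares at Touch (20.6% in Passerina, 21.8% in Moscato bianco) and at Soft (32.0% in Vermentino, 37.8% in Passerina) were in the columns where the most abundant gene, VIT_19s0014g02740, was listed at 0. From Soft to Harv the share went down in Glera (46.1% to 39.7%) and Moscato bianco (43.2% to 39.4%), and up in the other 3 cultivars. In Glera and Moscato bianco VIT_19s0090g01370 was listed at 0 at Harv, against 17395 to 38450 FPKM in the other cultivars. The rises in Vermentino and Passerina start from the Soft columns with VIT_19s0014g02740 listed at 0. These directions may therefore depend on values listed at 0. The median FPKM of the 20833 genes was 10.96 ± 0.24 at Pea and 10.8 ± 0.33 at Touch, and 7.40 ± 0.24 at Soft and 6.83 ± 0.27 at Harv. The summed FPKM of a column, which is not a depth, ran from 770169 to 1062816.

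Stage was the main source of variation between columns. It held 68.8% of the variance of log2(FPKM + 1), cultivar held 19.0%, and 12.2% was left over. The first principal component, with 58.3% of the variance, ordered the stages in every cultivar. Berries at Touch lay 23.2% ± 7.9 of the way from Pea to Harv, and berries at Soft 74.3% ± 5.4. At Touch, Garganega lay lowest at 14.5% and Moscato bianco highest at 34.8%. At Soft, Garganega was again lowest at 66.3%, and Passerina was highest at 79.5%. At Harv the columns lay between 92.9% (Passerina) and 102.0% (Moscato bianco).

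**Figure D1:**
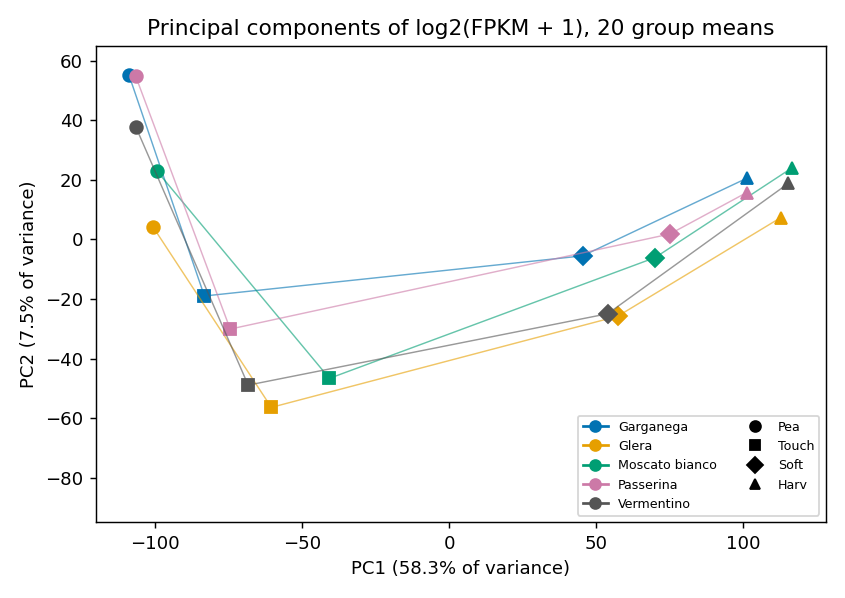
Principal components of log2(FPKM + 1) for the 20 columns, with the share of variance on each axis, colours for cultivars, symbols for stages and lines joining the stages of a cultivar. The first component (58.3%) runs from Pea on the left to Harv on the right, with the widest gap between Touch and Soft.

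**Figure D2:**
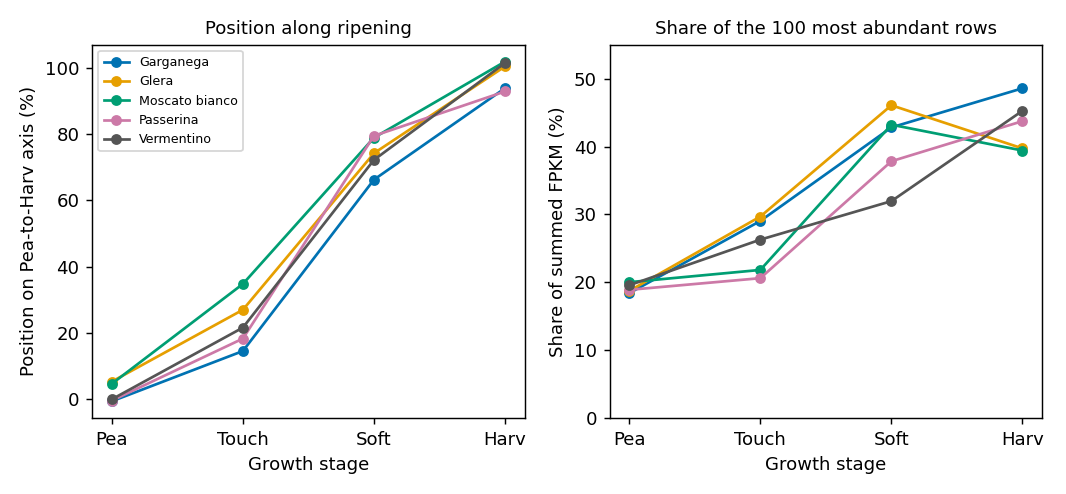
Position of each column on the line from Pea to Harv in percent (left) and percent of summed FPKM in the 100 most abundant genes (right), by stage, with a line for each cultivar. Positions at Touch run from 14.5% to 34.8%. The mean share of the 100 genes, chosen anew in each column, rises from 19.1% at Pea to 43.3% at Harv.

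From Pea to Touch, a comparison between younger and older green berries, more genes fell than rose. Of 1648 called genes, 445 rose and 1203 fell, with median log2 changes of 1.34 and -1.46. The same direction in all 5 cultivars was found for 428 of the rising and 1158 of the falling genes. VIT_19s0090g01000 was listed at 0 in all 5 columns at Pea and stood between 2709 FPKM (Moscato bianco) and 5101 FPKM (Garganega) at Touch. It then stood at 257 to 425 FPKM at Soft and 166 to 271 FPKM at Harv. VIT_01s0011g05110 went from 0.338 to 14.1 FPKM at Pea to between 1.32 FPKM in Garganega and 2336 FPKM in Moscato bianco at Touch. Its log2 change was 6.28 (SE 2.25, adjusted p = 0.0443). It was listed at 0 in Moscato bianco at Soft and Harv. VIT_19s0027g01810 fell by 5.60 on the log2 scale (SE 0.72, adjusted p = 4.7e-05), from 123 ± 109 FPKM at Pea to at most 0.487 FPKM in any cultivar at Touch. VIT_13s0019g01520 fell by 5.48 (SE 0.69, adjusted p = 4.04e-05), from 110 ± 94 FPKM to at most 0.614 FPKM. Both falling genes were higher at Pea than at Touch in all 5 cultivars, but their Pea values were uneven. VIT_19s0027g01810 stood at 172 to 247 FPKM in Vermentino, Garganega and Passerina, and at 7.02 FPKM in Glera and 8.52 FPKM in Moscato bianco. For VIT_13s0019g01520 the values were 171 to 185 FPKM in the same cultivars, 7.91 FPKM in Glera and 7.12 FPKM in Moscato bianco.

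Changes of any size were balanced from Pea to Touch, with 3483 genes higher and 3364 lower past the adjusted p alone, and a median log2 change over all genes of 0.02. The call of VIT_01s0011g05110 was lost without Glera (adjusted p = 0.13), without Passerina (adjusted p = 0.147) and without Vermentino (adjusted p = 0.126). It was also lost in 5 other alternatives. The log2 change of the gene was 5.84 to 7.65 with 1 cultivar left out. Over the alternatives its adjusted p ran from 0.00249, without Moscato bianco, to 0.624, in a test against a 2-fold change. With the 2 stages alone it was 0.00772. A test against a 2-fold change left 351 called genes, and a pseudocount of 5 left 780.

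The transition from Touch to Soft, which spans the onset of ripening, changed the most genes. Of 3918 called genes, 748 rose and 3170 fell, and 3766 of them moved in the same direction in all 5 cultivars. Large changes were also most frequent here, with 72 genes up and 52 down by at least 16-fold. VIT_05s0049g00770 went from 2.56 ± 1.95 FPKM at Touch to 2436 ± 1220 FPKM at Soft, a log2 change of 9.33 (SE 0.49, adjusted p = 3.54e-09), and stood at 1855 ± 836 FPKM at Harv. The joined row VIT_05s0094g00330,VIT_05s0094g00340 went from 0.193 to 26.5 FPKM at Touch to 2752 to 9721 FPKM at Soft, with a log2 change of 9.21 (SE 1.88, adjusted p = 0.000707). It was listed at 0 in Passerina at Harv, a value that enters the pooled spread. Without Passerina its adjusted p was 4.52e-07, and with any other cultivar left out it was 0.00483 to 0.00544. VIT_18s0122g00290 fell by 6.57 on the log2 scale (SE 0.25, adjusted p = 2.61e-10), from 139 ± 54 FPKM to at most 1.34 FPKM in any cultivar. VIT_05s0049g00520 stood at 19.7 to 428 FPKM at Touch and was listed at 0 in all 5 columns at Soft and all 5 at Harv. These 4 genes moved in the same direction in all 5 cultivars.

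The balance of rising and falling genes from Touch to Soft depended on the scale of the columns. With FPKM as deposited, 80.9% of called genes fell, 2022 genes were higher and 10485 lower past the adjusted p alone, and the median log2 change over all genes was -0.31. With columns scaled to equal medians, 1391 genes rose and 1749 fell (55.7% falling), and the median change was 0.07. Quantile normalization gave 1170 rising and 1755 falling genes (60% falling). Scaled by the sum over all but the 100 most abundant genes, 911 rose and 2477 fell (73.1% falling), with a median change of -0.16. Of the 3918 genes called on the deposited scale, 2497 kept their call with equal medians and 2478 with quantile normalization, and 0 were called in the opposite direction under either. A test against a 2-fold change left 310 rising and 1207 falling genes.

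**Figure D3:**
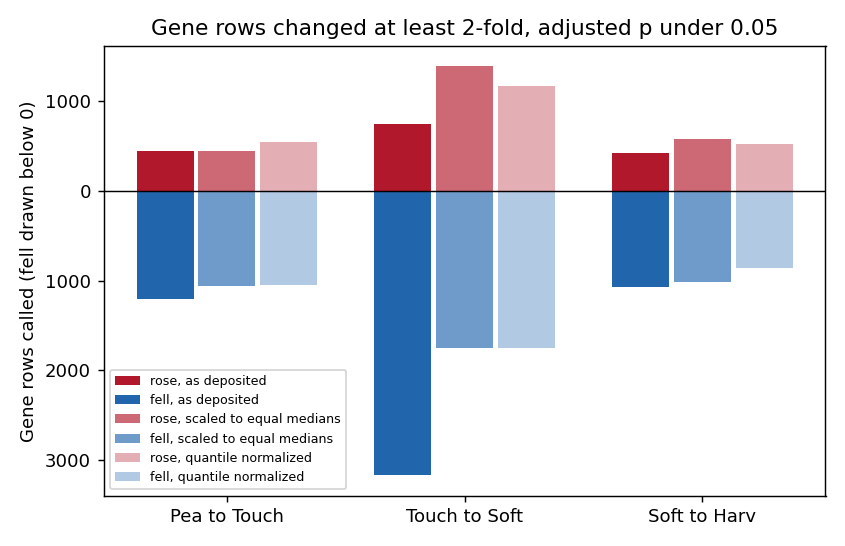
Number of called genes that rose (above 0) and fell (below 0) in each transition, with FPKM as deposited, with columns scaled to equal medians and after quantile normalization. From Touch to Soft the falling genes number 3170 as deposited and 1749 with equal medians; in the other transitions the bars differ less between scales.

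Between Soft and Harv, the last phase before picking, 428 genes rose and 1073 fell, and 1438 of these 1501 genes moved in the same direction in all 5 cultivars. Past the adjusted p alone, at any size, 3471 genes were higher and 4084 lower at Harv. Of the called genes, 0 rose and 11 fell by at least 16-fold. VIT_14s0171g00100 rose from 25.9 ± 23.4 to 282 ± 160 FPKM, a log2 change of 3.75 (SE 0.49, adjusted p = 6.69e-05). It had stood at 11.5 ± 5.0 FPKM at Pea and 1.54 ± 0.81 FPKM at Touch. VIT_14s0128g00570 went from between 0.0436 and 50.1 FPKM at Soft to between 0.192 and 398 FPKM at Harv, with a log2 change of 3.54 (SE 0.97, adjusted p = 0.0108). In Glera it stayed near 0, at 0.0605 FPKM at Soft and 0.192 FPKM at Harv (log2 change 0.17). The other cultivars stood at 21.1 to 398 FPKM at Harv. VIT_01s0137g00240 fell by 4.80 (SE 0.55, adjusted p = 2.8e-05), from 151 ± 132 to 3.94 ± 3.56 FPKM. VIT_06s0004g00070 fell by 4.65 (SE 0.54, adjusted p = 3.2e-05), from 93.3 ± 42.4 to 3.06 ± 2.69 FPKM. It had stood at 4.04 ± 2.28 FPKM at Pea and 10.9 ± 12.5 FPKM at Touch.

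The call of VIT_14s0128g00570 was lost without Garganega (adjusted p = 0.0528), without Moscato bianco (adjusted p = 0.0748) and without Vermentino (adjusted p = 0.0582). It was also lost in a test against a 2-fold change (adjusted p = 0.495). Its lowest adjusted p over the alternatives was 0.00261, in the run without Glera. The test against a 2-fold change left 167 called genes in this transition, and a pseudocount of 5 left 663.

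In total, 5514 genes were called in at least 1 transition and 151 in all 3. The most frequent course was a fall from Touch to Soft with no other call, in 2169 genes. A fall from Pea to Touch alone was found in 673 genes and a rise from Touch to Soft alone in 467. Of the genes that fell from Touch to Soft, 544 fell again to Harv, where independent lists would share 163.3, and 29 rose, where independent lists would share 65.1. Rises from Touch to Soft were followed by a further rise in 99 genes (15.4 for independent lists) and by a fall in 90 (38.5). Earlier, 391 genes fell from Pea to Touch and again to Soft (183.1 for independent lists), and 147 rose to Touch and fell to Soft (67.7). The numbers for independent lists run over all 20833 genes, also those with low FPKM, which reach a call less easily. With a filter of 5 FPKM, 3753 of the 3918 calls from Touch to Soft were kept. An excess can therefore come in part from which genes can be called at all, also in the splits below.

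Adjacent transitions share the columns of the middle stage, which ties their chance values together. Chance error in these columns enters the 2 changes with opposite signs, so it favours a rise followed by a fall, or the reverse. This tie works against repeated falls and repeated rises, and so does not account for their excess. A simulation without any stage change gave 0 such genes, but it calls almost no genes at all and so does not measure that tie. When the transitions were taken from different cultivars, in 20 splits into 2 and 3 cultivars, the genes that fell to Soft and again to Harv numbered 319 in the median (range 0 to 642), where independent lists would share 95.1. For rises that were followed by rises, the median was 41 (0 to 102) against 7.2, and for rises followed by falls 34.5 (0 to 81) against 20.9. For falls to Soft followed by rises to Harv, it was 10.5 (0 to 36) against 33.1. Falls to Touch followed by falls to Soft had a median of 204.5 (55 to 453) against 117.3, rises followed by falls 74.5 (9 to 181) against 43.4, and rises followed by rises 37 (4 to 91) against 9.6. Genes that fell to Touch and rose to Soft numbered 56, above the 43.2 of independent lists, but 21.5 (3 to 53) in the splits, below 26.4. In each of these pairs the range over splits includes the median number for independent lists. That number was worked out for each split, but only its median was kept. The range therefore does not tell how many splits lay above or below their own number.

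In each transition, more genes changed at least 2-fold in exactly 1 cultivar than in all 5. With a 1.5-fold rule this order did not hold from Touch to Soft, with 3551 genes in exactly 1 cultivar and 3555 in all 5. From Touch to Soft, 1756 of the 8291 genes with such a change in at least 1 cultivar changed in the same direction in all 5, 338 up and 1418 down. From Pea to Touch the number was 617 of 4855 (154 up, 463 down), and from Soft to Harv 332 of 5248 (84 up, 248 down). Changes of that size in exactly 1 cultivar were found for 2010 genes from Pea to Touch, 2764 from Touch to Soft and 2356 from Soft to Harv. Opposite changes of at least 2-fold in different cultivars were less frequent, with 186, 246 and 176 genes in the transitions in that order. Pearson correlations of the log2 changes between pairs of cultivars, taken across genes, which are not independent replicates, had medians over 10 pairs of 0.69, 0.76 and 0.59. These counts have no test, since each cultivar has 1 value at a stage.

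Passerina changed least from Soft to Harv. In it 913 genes moved at least 2-fold, against 2408 in Garganega, 2455 in Moscato bianco, 2487 in Glera and 2873 in Vermentino. In the preceding step from Touch to Soft, Passerina had the most such genes, 5497, and the others had between 3883 (Glera) and 4794 (Garganega). Without Passerina, the genes changed from Soft to Harv in all of the remaining 4 cultivars numbered 738 in place of 332. From Pea to Touch, the counts ran from 1740 in Glera to 2600 in Vermentino.

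A small set of genes set a cultivar apart at every stage. A margin of at least 2-fold above the highest or below the lowest of the other 4 cultivars, at all 4 stages, was found for 77 and 99 genes. Glera had 23 high and 21 low genes, Moscato bianco 15 and 30, Vermentino 12 and 23, Garganega 14 and 16, and Passerina 13 and 9. With cultivar names permuted within each stage, the total over cultivars was 0 in the median of 100 draws and at most 45, against 176 in the data. VIT_08s0007g00630 stood at 9.63 to 18.3 FPKM in Passerina and was listed at 0 in all columns of the other cultivars. VIT_13s0067g02040 stood at 20.7 to 32.6 FPKM in Moscato bianco and at 0.188 to 1.92 FPKM elsewhere. Both of the genes with the widest margin below the others were low in Glera. VIT_00s0346g00050 was listed at 0 in Glera at all 4 stages and stood at 35.2 to 146 FPKM in the other cultivars. VIT_09s0018g01410 reached at most 0.959 FPKM in Glera, against 32.8 to 218 FPKM elsewhere.

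Among the 99 low genes, 48 stayed under 1 FPKM at every stage in the cultivar concerned, and for 31 of the 77 high genes all other cultivars stayed under 1 FPKM. Fewer stages make the rule easier to meet. Without Harv the total was 269, with 60 genes for Vermentino (53 without Pea), 48 for Garganega and 35 for Passerina (41 without Touch). With a pseudocount of 5 the total was 30.

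The gene with the highest mean over the 20 columns was VIT_19s0014g02740, at 47311 FPKM. It was not called in any transition. Its values listed at 0 enter both the changes and the pooled spread, so the missing call does not show that the gene was unchanged. At Soft it stood at 139535 FPKM in Garganega, 138458 FPKM in Glera and 116733 FPKM in Moscato bianco, and was listed at 0 in Vermentino and Passerina. At Touch it was listed at 0 in Moscato bianco and Passerina. It stood there at 43175 FPKM in Vermentino, 92996.5 FPKM in Garganega and 105692 FPKM in Glera. At Pea it stood between 3041 FPKM in Vermentino and 13827 FPKM in Moscato bianco. Of 201 genes that reached 1000 FPKM in a column, 12 were listed at 0 in at least 1 column, with 46 such values together.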

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

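All tests on Passerina in this part were chosen after the result was seen. The 5 values at a stage or in a transition were searched for a cultivar far from the rest in 45 sets; 5 sets had such a value, and chance alone gives about 2.2.

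Passerina had 913 genes changed at least 2-fold from Soft to Harv, while the others had 2408 to 2873. Less scatter of its values with an equal step in ripening is argued against, because the step along the line from Pea to Harv was 13.4% in Passerina and 23.0% to 29.3% in the others. A closer spacing of its Soft and Harv berries in ripening may account for the count: from Touch to Harv, 6335 genes changed in Passerina, within the 6240 to 6662 of the others. Whether a library of another stage was averaged into a Passerina column cannot be told apart from this, since 0 columns hold a single library. A difference between cultivars in the pace of late ripening, and different sampling dates, also stay open as untested.

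In Moscato bianco at Pea, the most abundant gene held 1.70% of the summed FPKM, against 0.807% to 0.891% in the other cultivars. The 10 most abundant genes held 6.81% there, against 5.62% to 5.94% elsewhere. The log2 change of VIT_01s0011g05110 from Pea to Touch was 0.79 in Garganega and 7.27 to 8.05 in the other cultivars. The log2 change of VIT_05s0094g00330,VIT_05s0094g00340 from Touch to Soft was 11.17 in Vermentino and 8.47 to 9.17 in the others.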

How the results depend on the processing

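The alternatives chosen after seeing the data were the scaling without the 100 most abundant genes, the run without abundant genes listed at 0, and the leave-one-out counts of changes shared by all cultivars. Of all values recomputed under an alternative, 395 kept their direction and side of the threshold or stayed within 1.5 times, 12 lost their call, 71 moved by more and 0 reversed. Only the named genes could be marked as having lost their call or reversed. The 12 named genes kept their call in 189 of 201 pairs of a gene and an alternative. VIT_19s0090g01000, VIT_01s0011g05110 and VIT_05s0094g00330,VIT_05s0094g00340 were absent from the run without abundant genes listed at 0, which is not counted for them. Leaving out each cultivar gave 1527 to 1696 called genes from Pea to Touch, 3613 to 3960 from Touch to Soft and 1300 to 1779 from Soft to Harv. Stage held 64.2% to 66.4% of the variance and cultivar 20.7% to 22.9% with a pseudocount of 0.1 or quantile normalization, called unchanged when within 5 percentage points. No paired analysis was possible because the columns carry no replicate number, as far as a block of libraries goes; the cultivar term already compares stages within cultivars. Without that term, 1476, 3688 and 1251 genes were called in the transitions in order, and with the 2 stages alone 1675, 3848 and 1438. The gene list tests were not run, since the identifiers have no names here. Depth is unknown, so what it limits could not be worked out; low FPKM carry the most counting error.

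The pseudocount and the fold rule set the counts by construction. The pseudocount decides how far genes with low FPKM can move, and the fold rule how large a change must be at any level. With a pseudocount of 0.1, 2534 genes were called from Pea to Touch (675 up, 1859 down) and 2804 from Soft to Harv (753 up, 2051 down). With a pseudocount of 5, the counts were 780 from Pea to Touch (260 up, 520 down), 2109 from Touch to Soft (1596 down) and 663 from Soft to Harv (195 up, 468 down). A test against a 2-fold change called 351 (66 up, 285 down), 1517 (310 up, 1207 down) and 167 (29 up, 138 down). From Touch to Soft, equal medians gave 1391 up and 1749 down, and quantile normalization 1170 up and 1755 down; the cause was not tested by these alternatives.

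Genes changed in all 5 cultivars numbered 1188, 2690 and 744 in the transitions in order with a pseudocount of 0.1, 274, 903 and 130 with a pseudocount of 5, and 1596, 3555 and 1005 with a 1.5-fold rule. Genes changed in exactly 1 cultivar numbered 1063, 1668 and 1197 with a pseudocount of 5, and 4032 from Soft to Harv with a 1.5-fold rule. From Soft to Harv, leaving out each cultivar gave 367 to 738 genes changed in all others, the highest without Passerina. Fewer cultivars make that rule easier to meet, but the other cultivars left out gave smaller rises; the cause of the difference was not tested.

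Genes that set a cultivar apart numbered, for Garganega, Glera, Moscato bianco, Passerina, Vermentino and in total, 85, 99, 136, 54, 116 and 490 with a pseudocount of 0.1. They numbered 2, 10, 9, 3, 6 and 30 with a pseudocount of 5. With a 4-fold rule they numbered 3, 7, 7, 2, 5 and 24, and with a 1.5-fold rule 84, 103, 113, 74, 97 and 471. Leaving out each stage gave 34 to 48 for Garganega, 24 to 41 for Passerina, 37 to 60 for Vermentino and 194 to 269 in total. The total was highest without Harv, and fewer stages make the rule easier to meet.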

Other observations

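The tests on the balance of rising and falling genes and on values of 0 were chosen after the results were seen; those on neighbouring identifiers, on Moscato bianco and on other splits were not.

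Genes with neighbouring identifiers changed together more often than genes drawn at random. Positions were not used here, so neighbours are rows that follow each other in the numbering of the identifiers. From Touch to Soft, 632 of 15741 neighbouring pairs had the same call, against 385.02 in the mean and 438 at most over 1000 permutations of the calls. The excess was found for rising pairs (76 against a mean of 20.24) and for falling pairs (556 against 364.79), and pairs with opposite calls were fewer (121 against 172.36). The permutation p was 0.001 for the same call, the smallest that the permutations can give. Runs of at least 5 neighbours with the same call numbered 2 for rises and 7 for falls, the longest with 7 genes. Genes high or low in the same cultivar were neighbours in 7 pairs, against 0.12 in the mean and 2 at most by permutation (permutation p = 0.001, the smallest possible). These values are consistent with the hypothesis that neighbouring genes, such as tandem copies, share their course. Fragments shared between near-identical neighbours could give the same excess and were not separated from it.

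Moscato bianco lay furthest along the line from Pea to Harv at Touch. One hypothesis was that part of its berries were already soft. A mixture of its own Soft values with the mean Touch values of the other cultivars was fitted to 131 rising genes and gave a share of 2.86%. Such a share predicts a median log2 level of -0.03 in 1198 falling genes, and -0.47 was observed. The difference of -0.44 lies outside the -0.12 to 0.10 of the other cultivars, which argues against such a mixture as the whole account. A general lead of this cultivar in development at that sampling stays open as untested.

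More genes fell than rose from Touch to Soft, 3170 against 748. If the growing share of the most abundant genes were the whole cause, a falling share of calls of 60% or less was predicted. Scaled by the sum over all but the 100 genes with the highest mean over the columns, 73.1% of calls still fell. As deposited, however, 73.0% of calls fell from Pea to Touch and 71.5% from Soft to Harv, with median log2 changes of 0.02 and -0.02. A share of that size thus occurs with little shift of the median, so the 60% mark does not decide the question. Scaling by the sum over the other genes did move the median log2 change of all genes from -0.31 to -0.16, so abundant genes may hold part of the shift. Equal medians brought the falling share to 55.7%, but that scaling moves the balance toward even by construction, so it does not test whether a shift common to most genes was the cause. Whether there was such a shift, technical or a true decline of most transcripts relative to total RNA, stays open.

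Among values for which the other cultivars had a median of at least 10 FPKM at the stage, exact 0 was most frequent at the highest levels; lower levels were not compared. Where the other cultivars had a median of 10000 FPKM or more at the stage, 8 of 73 values (10.96%) were listed at 0, against 12 of 26510 (0.0453%) at 100 to 1000 FPKM. These 8 values came from 4 genes, with 4 of them from VIT_19s0014g02740 and 2 from VIT_19s0090g01370, so they are not independent. Failed estimates for genes with very many fragments may account for them, which stays a hypothesis. A lack of the transcript in the cultivar is argued against for most of them, since 15 of 17 such values at a level of 3000 FPKM or more, in 9 genes, belonged to a cultivar that reached 100 FPKM in that gene at another stage.

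Each count of called genes was set against other splits of the columns, most of which do not keep the pairing of stages by cultivar. Such splits put both stages of some cultivars on the same side. The stage change then enters their residual spread, which lowers their counts in advance. Of 100 splits of the 10 columns of a transition into 5 and 5, drawn from 126, only the real split, 1 of 100, gave as many called genes. From Pea to Touch the real count was 1648 and the highest other 984. From Touch to Soft these were 3918 and 2339, and from Soft to Harv 1501 and 869. Among 11 of the drawn splits that part the stages of every cultivar, the real one included, the highest other counts were 1, 0 and 0. Those 11 alone are too few for a share under 0.05, since the smallest they can give is 1 of 11. The splits therefore do not exclude chance.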
